A study of Mus musculus with 20 samples.

How the data were processed

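RNA was sequenced from epididymal (eWAT) and inguinal (iWAT) white adipose tissue of mice fed a high-fat diet for 18 weeks from 6 weeks of age. The 20 libraries formed 4 groups of 5, which the series describes as biological replicates. In each depot, mice with a floxed Stat1 gene and an Adipoq-driven Cre recombinase (fKO) were compared with floxed mice without Cre (Ctrl). Per the labels, the mice were C57BL/6J and 6.5 months old, RNA came from pieces of about 40 mg, and sequencing gave about 20 M paired-end reads of 76 bp per library. Per the submitters' processing notes, reads were aligned to mm10 with HISAT2 and gene abundances were computed with StringTie. The annotation release is not given in the sources used here.

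The deposited tables, 1 per depot, hold FPKM values (fragments per kilobase of gene, scaled to the sequencing depth of the library) as computed by the authors for each library, with no further scaling between libraries shown. They listed 52539 gene entries for eWAT and 52542 for iWAT, of which 7 and 10 had a missing value and were left out. In each depot, 181 entries shared a symbol with another and were summed by symbol. GENCODE M21 held 52392 of the eWAT identifiers and 52395 of the iWAT identifiers, and gave the coordinates. Pearson's r between pairs of libraries on the log2 scale ranged from 0.952 to 0.994, and 0 pairs held identical values.

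Because the tables hold no counts, depth was estimated from the low values of single-exon genes multiplied by gene length, whose commonest value in each library was taken as 1 fragment. In single libraries, 10.7% to 16.4% of these low values lay at that step, 6.21% to 9.34% at 0.5 and 4.51% to 6.52% at 2 times that step, so values are not all whole numbers of fragments and the absolute depth is approximate. The estimate was 19.0 ± 3.05 M fragments (SD, n = 5) in eWAT Ctrl and 16.6 ± 1.78 in eWAT fKO (exact two-sided permutation p = 0.151). It was 19.7 ± 11.1 M in iWAT Ctrl and 27.5 ± 12.1 M in iWAT fKO (exact two-sided permutation p = 0.310). Single libraries ranged from 11.4 to 43.1 M in iWAT and from 14.4 to 23.5 M in eWAT. No counting interval was attached to single values, since the counts themselves are not in the tables.

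Genes with a mean of at least 1 FPKM over the 10 libraries of a depot were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend). Each depot was fitted alone, fKO against Ctrl, without covariates. Differences are given as fKO minus Ctrl, with the standard error (SE) from the same fit. The difference between depots was tested as an interaction over all 20 libraries. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Single genes and list means were also tested with exact two-sided permutation tests over the 252 splits of 10 libraries into 5 and 5, for which the smallest p is 0.00794. Tests of the difference between depots for list means used all 63504 combinations of such splits in the 2 depots.

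Gene lists for pathways and cell types were written before the data were examined, 37 in all. Lists with at least 5 measured members were tested with camera in limma at its preset inter-gene correlation of 0.01, adjusted over 69 tests (36 in eWAT, 33 in iWAT). Beside it stand camera with an estimated correlation and the rotation test fry. Members were also counted after adjustment over the list alone.

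The genes named were chosen by a rule set before the data were examined. It takes Stat1, then up to 10 genes that rose most and up to 10 that fell most among those past the threshold, leaving out predicted genes, receptor segments and genes without a symbol. With fewer than 5 genes past the threshold, the 10 of lowest p are named as values that did not pass. From each list called or discussed, up to 4 members past the threshold are named, or the 2 of highest mean value where none passed. 11 genes are always named: Adipoq, Lep, Ifng, Cd274, Ciita, Cxcl9, Irf1, Adgre1, Itgax, Ucp1 and Slc2a4. For the interaction, up to 6 genes past the threshold are named. For members of lists, the threshold was read as that adjusted over the list alone, and clone-based names were treated as lacking a symbol. Both readings, and the naming of the predicted genes that passed, came after the data were seen.

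The procedure was tested on simulated data of the same design with known changes. For log2 changes of 0.5, 1 and 2, the test recovered 29.9%, 68.7% and 86.4% of the changed genes in simulated eWAT, with 5 false calls. In simulated iWAT it recovered 35.8%, 65.7% and 90.9%, with 6 false calls. For the interaction it recovered 22.2%, 74.4% and 91.4%, with 11 false calls. Each simulated depot held 67, 67 and 66 genes with these changes, besides a shifted list of 40 members. With so many changed genes the adjusted threshold is less strict than in the real data, where 2 genes passed in eWAT and 4 in iWAT. The shares recovered therefore need not hold there. The list shifted by -0.4 was the 1 list called in each simulated depot, with recovered means of -0.39 and -0.41. Simulated genes were drawn independently of each other, whereas members of real lists vary together (estimated correlation up to 0.970, blood genes in eWAT). The simulation therefore does not show how many lists camera calls falsely at the preset correlation in the real data.

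Alternatives planned before the data were examined were a pseudocount of 0.1, no filter, a filter at a mean of 5, median-of-ratios rescaling, quantile normalization, array weights, a fit without trend and with robust variances, all 20 libraries in 1 fit, the replicate number as a block, an estimated inter-gene correlation, lists without shared members, and leaving out each replicate in turn. Added after seeing the data were a fit to protein-coding genes only and covariates for the macrophage, skeletal muscle, blood and mesothelial list means, log2 depth, and depth class (under or over 15 M fragments). The planned count-based tests were not run because the tables hold FPKM.

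Replicate numbers 1 to 10 recur in both depots, and each number carries the same genotype in both, which would hold if a number marked 1 animal. The tables alone do not show that a number marks 1 animal: eWAT and iWAT libraries with the same number had correlations of -0.0582 to 0.453 across genes after centring on the group, 8 of the 10 were over 0.1, and 3 of 10 eWAT libraries were matched best by their own number. The block was therefore kept as an alternative. Pseudogenes were matched to their parent transcripts with BLAST 2.17.0. Other computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.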

Results

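Gene expression was measured by RNA-seq in 20 mouse adipose tissue libraries, 10 from epididymal white fat (eWAT) and 10 from inguinal white fat (iWAT). Each depot held 5 libraries from mice lacking Stat1 in adipocytes (fKO, floxed Stat1 with Adipoq-driven Cre) and 5 from floxed mice without Cre (Ctrl), all on a high-fat diet. STAT1 is the transcription factor that carries interferon signals to the nucleus. The comparisons ask which genes depend on adipocyte Stat1 in obesity, with the tissue's inflammation and insulin sensitivity as the question named in the series title. Values are FPKM, and the approximate depth estimated from them ranged from 14.4 to 23.5 M (mega) fragments per library in eWAT and from 11.4 to 43.1 M in iWAT.

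Stat1 RNA was lower in fKO in both depots. In eWAT, Stat1 (ENSMUSG00000026104, mm10 chromosome 1, 52119440 to 52161865, plus strand) was at 19.6 ± 2.59 FPKM in Ctrl and 6.90 ± 2.76 in fKO (SD, n = 5 each), which is 35.2% of the Ctrl mean. In iWAT it fell from 18.0 ± 2.80 to 4.23 ± 1.12 FPKM (SD, n = 5 each), or 23.5% of the Ctrl mean. All 5 fKO libraries lay below all 5 Ctrl libraries in each depot, with ranges of 3.56 to 10.6 against 16.3 to 23.5 FPKM in eWAT and 3.40 to 6.15 against 14.6 to 21.4 FPKM in iWAT. The iWAT difference of -1.87 ± 0.15 (log2, SE) passed the limma test over all genes (adjusted p = 0.000417), while the eWAT difference of -1.45 ± 0.22 did not (adjusted p = 0.15). The exact permutation p was 0.00794 in each depot, the smallest that 5 against 5 can give. The difference between depots did not pass the test (iWAT minus eWAT -0.43, interaction adjusted p = 1). In eWAT the adjusted p for Stat1 was 0.0424 without fKO replicate 2 and 0.00254 when all 20 libraries were fitted together.

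**Figure D1:**
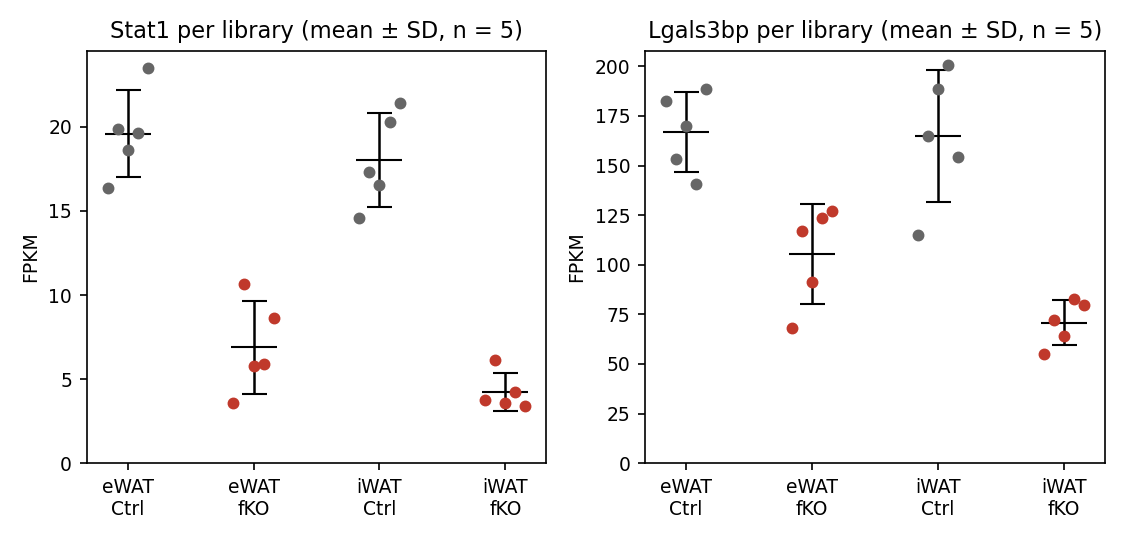
Stat1 and Lgals3bp expression (FPKM, linear axis from 0) in each library of eWAT and iWAT, Ctrl and fKO. Points are libraries, and bars give the mean ± SD of 5; for both genes, all 5 fKO libraries lie below all 5 Ctrl libraries in each depot.

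In eWAT, Stat1 loss in adipocytes went with lower values of interferon-inducible genes as a group and few changes in single genes. Of 41 measured genes of the type I interferon response, 39 had values below 0, with a mean log2 difference of -0.33 ± 0.12 (SE between libraries, n = 5 per group). They included Usp18 (-0.70 ± 0.18), Lgals3bp (-0.69 ± 0.17), Ifit1 (-0.67 ± 0.17) and Ifit3 (-0.66 ± 0.16). Lists of lipid synthesis, mesothelial, oxidative phosphorylation and resident macrophage genes lay higher, and general and lipid-associated macrophage lists lower. These calls were made at a preset correlation, and 0 lists passed with an estimated one.

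The gene-wise test in eWAT covered 14331 genes, of which 1 rose and 1 fell. AC156572.1 (ENSMUSG00000113637, chromosome 13, 62813076 to 62814787), a processed pseudogene whose sequence is 98.4% identical to Me1, rose from 4.75 ± 1.36 to 12.9 ± 0.708 FPKM (SD, n = 5 each), a log2 difference of 1.30 ± 0.14 (adjusted p = 0.0137). Gm1866 (ENSMUSG00000082070, chromosome X, 114592048 to 114592524), a processed pseudogene 99.2% identical to Acp1, fell from 4.19 ± 0.505 to 1.29 ± 0.378 FPKM (SD, n = 5 each), a log2 difference of -1.19 ± 0.13 (adjusted p = 0.0137). Both are predicted or clone-named genes outside the naming rule and were named after their values were seen. At an unadjusted p under 0.05 stood 326 genes, 2.27% of those tested, 116 with higher and 210 with lower values. That share is below the 0.05 that chance alone would give on average. Neither pseudogene remained past the threshold when Ctrl replicate 3, 4, 7 or 8 or fKO replicate 6 or 10 was left out (0 genes passed in each case), and 4 genes passed without fKO replicate 2. With log2 depth or the blood list mean as a covariate, both added after seeing the data, 0 genes passed.

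Predicted genes aside, the genes of lowest p that did not pass in eWAT were led by Fmo3, a flavin-containing monooxygenase, at 0.647 ± 0.174 FPKM in Ctrl and 3.50 ± 1.34 in fKO (SD, n = 5 each), a log2 difference of 1.41 ± 0.18 (adjusted p = 0.0577). Without fKO replicate 2 (1.52, adjusted p = 0.0424) or 5 (1.25, adjusted p = 0.0433) it passed, and without other libraries its limma adjusted p went up to 0.251. It also passed with the macrophage list mean as a covariate, added after seeing the data (1.32, limma adjusted p = 0.0416). With all 20 libraries in 1 fit it passed too (limma adjusted p = 9.65e-05), but that fit pools its spread with iWAT, where Fmo3 lay far under the filter. Ptprd, a receptor tyrosine phosphatase (0.97 ± 0.18), and the zinc finger gene Zfp949 (0.57 ± 0.10) followed with higher values and an adjusted p of 0.382 each. Besides Stat1, lower values were seen for the guanylate-binding protein gene Gbp10 (-0.95 ± 0.21), Hypk (-1.15 ± 0.27), the histone deacetylase gene Hdac9 (-1.14 ± 0.28), Ifit3 (-0.66 ± 0.16), Ifit3b (-0.63 ± 0.15) and Dpp8 (-0.52 ± 0.13), each at an adjusted p of 0.959.

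Among the fixed lists in eWAT, the type I interferon response was lower as a group (camera adjusted p = 3.64e-17 and adjusted p = 0.369 with an estimated correlation). None of its 41 members passed over all genes, while 11 fell when adjusted over the list alone, among them Usp18, Lgals3bp, Ifit1 and Ifit3. Its mean was lower than in every Ctrl library in 4 of 5 fKO libraries (exact permutation p = 0.0159). The interferon-gamma response, with 25 of 27 members below 0 and a mean of -0.29 ± 0.17, was lower by camera (adjusted p = 9.06e-07 and adjusted p = 0.464 with an estimated correlation), with an exact permutation p of 0.159. Of the fKO libraries, 4 lay below and 1 above all Ctrl libraries in this list mean, and without fKO replicate 1 it was -0.19 (camera adjusted p = 1.73e-05). Adjusted over the list alone, 2 of its members fell, Gbp10 and Gbp6 (-0.80 ± 0.21). The MHC class I pathway had all 25 members below 0 with a mean of -0.22 ± 0.14 (camera adjusted p = 1.94e-05 and adjusted p = 0.464 with an estimated correlation), among them B2m (-0.20 ± 0.13) and H2-D1 (-0.25 ± 0.14). Its values lay furthest down in fKO replicates 1 (-0.67 from the Ctrl mean) and 5 (-0.41), against -0.06 to 0.09 in the other fKO libraries, and its mean was -0.10 without fKO replicate 1 (camera adjusted p = 0.00210). The MHC class II list was not called (mean -0.05 ± 0.25, camera adjusted p = 0.917), and camera's direction for it was up while its mean and median (-0.11) lay below 0.

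Lists of oxidative, lipogenic and lipolytic genes in eWAT lay above 0, and that of cholesterol synthesis lay below 0 without a call (-0.10 ± 0.19). Oxidative phosphorylation and TCA cycle genes had 36 of 38 members above 0, with a mean of 0.13 ± 0.10 (camera adjusted p = 8.78e-09 and adjusted p = 0.464 with an estimated correlation), among them Cox8a (0.19 ± 0.17) and Atp5b (0.13 ± 0.14). Lipogenesis had 21 of 24 above 0 and a mean of 0.24 ± 0.16 (camera adjusted p = 1.86e-08 and adjusted p = 0.388 with an estimated correlation), with Scd1, the stearoyl-CoA desaturase (0.50 ± 0.54), and Dgat2 (0.11 ± 0.16). Fatty acid oxidation had a mean of 0.11 ± 0.08 (camera adjusted p = 0.00132 and adjusted p = 0.464 with an estimated correlation), with Acadm at 0.11 ± 0.12 and Etfb at -0.01 ± 0.12. The adipocyte list (0.22 ± 0.30, Fabp4 0.17 ± 0.57) had a camera adjusted p of 0.00139 and the lipolysis list (0.15 ± 0.20, Plin1 0.25 ± 0.26, Pnpla2 0.22 ± 0.25) of 0.00327. With an estimated correlation their adjusted p values were 0.571 and 0.499. The adipocyte and lipolysis calls ended without fKO replicate 1 (means 0.07 and 0.06) or Ctrl replicate 8 (0.10 and 0.06). Their means were 0.14 and 0.10 without fKO replicate 5, 0.39 and 0.28 without Ctrl replicate 3, and 0.41 and 0.26 without fKO replicate 10. The fatty acid oxidation call ended without fKO replicate 2 (0.06), and the mean was also 0.06 without Ctrl replicate 8. Without fKO replicate 2 the oxidative phosphorylation mean was 0.08. With the macrophage or the blood list mean as a covariate, both added after seeing the data, the adipocyte mean turned to -0.02 and -0.07 and the lipolysis mean to -0.0045 and -0.01, and neither list was called. None of the members of these lists passed over all genes or adjusted over the list alone. Fabp4 turned below 0 without fKO 1 (-0.03) or Ctrl 9 (-0.22), and Etfb above 0 without fKO 1, 5 or 10 (0.02 each), Ctrl 3 (0.00083) or Ctrl 9 (0.05).

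Immune cell lists in eWAT pointed both ways. Lipid-associated macrophage genes had a mean of -0.70 ± 0.66 (Lgals3 -0.81 ± 0.69, Ctsl -0.32 ± 0.29; camera adjusted p = 0.00624) and general macrophage genes -0.46 ± 0.51 (Lyz2 -0.64 ± 0.50, Tyrobp -0.69 ± 0.64; camera adjusted p = 0.00688). Inflammatory mediators (-0.32 ± 0.31, Ccl9 -0.53 ± 0.47, Saa3 0.38 ± 0.27; camera adjusted p = 0.0230), T and NK cell genes (-0.22 ± 0.23, Il7r -0.68 ± 0.62, Thy1 -0.03 ± 0.20; camera adjusted p = 0.0411) and proliferation genes (-0.33 ± 0.39, Pcna -0.35 ± 0.37, Stmn1 -0.27 ± 0.42; camera adjusted p = 0.00631) were also lower. Each of these lists had an adjusted p = 0.649 with an estimated correlation. The macrophage mean was carried by fKO replicates 1 (-1.74 from the Ctrl mean) and 5 (-1.27), while fKO replicates 2, 6 and 10 lay at 0.05, 0.14 and 0.54. Its call ended without fKO replicate 1 (-0.13, camera adjusted p = 0.352), fKO 5 (-0.25), Ctrl 4 (-0.38) or Ctrl 9 (-0.38), and its mean was -0.70 without Ctrl 3 or fKO 10. The lipid-associated macrophage call ended without fKO 1 (-0.28), fKO 5 (-0.48) or Ctrl 9 (-0.56), and that of inflammatory mediators without fKO 1 (-0.13), fKO 5 (-0.24), Ctrl 4 (-0.31) or Ctrl 8 (-0.17). The T and NK cell call ended without fKO 1 (-0.08), 5 (-0.16), 6 (-0.23) or 10 (-0.26) or Ctrl 4 (-0.20), 8 (-0.14) or 9 (-0.18), with means of -0.37 without fKO 2 and -0.33 without Ctrl 3. The proliferation call ended without fKO 1 (-0.07), fKO 5 (-0.19) or Ctrl 9 (-0.26), with means of -0.51 without Ctrl 3 and -0.55 without fKO 10. Immediate-early genes were lower too (-0.33 ± 0.24, Atf3 -0.98 ± 0.72, Dusp1 -0.23 ± 0.19; camera adjusted p = 0.00327 and adjusted p = 0.526 with an estimated correlation), with a mean of -0.17 without fKO 1. Resident macrophage genes lay higher in all 5 fKO libraries than in every Ctrl library (mean 0.20 ± 0.06, exact permutation p = 0.00794; camera adjusted p = 0.0213 and adjusted p = 0.369 with an estimated correlation). That list included Retnla at 1.16 ± 0.75 and Pf4 at -0.10 ± 0.21, and 6 of its 13 members were below 0. Its call ended without fKO 2 (0.16), fKO 10 (0.18), Ctrl 3 (0.20) or Ctrl 4 (0.14). Of the genes named here, Pf4 turned above 0 without fKO 1 (0.01) or 5 (0.03), Stmn1 without fKO 1 (0.03) and Thy1 without fKO 1 (0.09), Ctrl 8 (0.07) or Ctrl 9 (0.05). Ctrl replicate 3 stood apart from the other Ctrl libraries in the macrophage list mean (5.82 against 6.89 to 7.11, mean log2). Covariates added after seeing the data turned some of these means, and ended the calls concerned. With the blood list mean as a covariate the macrophage mean was 0.03, the lipid-associated macrophage mean -0.05 with camera's direction up, and the proliferation mean 0.07. With the macrophage list mean as a covariate the proliferation mean was 0.02. With array weights the T and NK cell mean was -0.03 with camera's direction up.

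Markers of other cells also differed in eWAT. Mesothelial genes, from the lining of the fat pad, had all 13 members above 0 and a mean of 0.37 ± 0.25 (Msln 0.63 ± 0.24, Upk3b 0.47 ± 0.31; camera adjusted p = 3.95e-07 and adjusted p = 0.464 with an estimated correlation). Ctrl replicate 9 lay at -0.82 from the Ctrl mean of this list, against 0.02 to 0.47 in the other Ctrl libraries, and without it the difference was 0.16 (camera adjusted p = 0.00258). Blood genes had all 6 above 0 and a mean of 0.78 ± 0.55 (Hba-a2 0.92 ± 0.56, Hbb-bs 0.79 ± 0.52; camera adjusted p = 5.61e-05 and adjusted p = 0.464 with an estimated correlation), with means of 0.49 without fKO 5 and 1.21 without fKO 10. Complement genes had a mean of 0.07 ± 0.11 (camera adjusted p = 0.0159 and adjusted p = 0.464 with an estimated correlation), and C6 rose when adjusted over the list alone (0.85 ± 0.21) though not over all genes. The complement call ended without fKO 2 (0.02), fKO 6 (0.03), fKO 10 (0.03), Ctrl 3 (0.05) or Ctrl 9 (0.05), with means of 0.16 without fKO 1 and 0.11 without Ctrl 7. Endothelial genes (0.09 ± 0.22, Cldn5 0.26 ± 0.29, Gpihbp1 0.33 ± 0.31) and extracellular matrix genes (Col3a1 0.09 ± 0.26, Sparc 0.16 ± 0.18) each had a camera adjusted p of 0.0410 and an adjusted p = 0.649 with an estimated correlation. The extracellular matrix list was called upward with a median of 0.06 and a mean just below 0 (-1.21e-05). Its call ended without fKO 6 (-0.06), fKO 10 (-0.08), Ctrl 3 (-0.10) or Ctrl 8 (0.02), and the mean lay between -0.02 (without fKO 2) and 0.13 (without fKO 1) when 1 of the other libraries was left out. Col3a1 turned below 0 without Ctrl 3 (-0.06), fKO 6 (-0.0058) or fKO 10 (-0.05). The endothelial mean turned to -0.05 without Ctrl 8, and its call ended without fKO 1 (0.04), fKO 2 (0.06), fKO 5 (0.02) or Ctrl 9 (0.04). Its mean was 0.15 without Ctrl 3 or fKO 6, 0.21 without Ctrl 7 and 0.20 without fKO 10. It turned to -0.03 with the macrophage and -0.04 with the blood list mean as a covariate, both added after seeing the data, and to -0.0026 with array weights. In all, camera called 21 of 36 lists in eWAT, 12 up and 9 down (14 without fKO 1 or Ctrl 9). With an estimated correlation 0 were called, by fry 0 and by the adjusted exact permutation test 0. Group size and the number of tests left the last test little room to call a list. Resident macrophage genes had the smallest possible exact permutation p (0.00794) and still an adjusted p of 0.274.

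In iWAT, interferon-inducible genes were lower in fKO as a group, and 1 of them passed the test over all genes. Lgals3bp, which encodes a secreted galectin-3-binding glycoprotein, fell from 165 ± 33.3 to 70.8 ± 11.3 FPKM (SD, n = 5 each), a log2 difference of -1.20 ± 0.16 (adjusted p = 0.0394). Type I interferon genes had a mean log2 difference of -0.40 ± 0.08 (SE between libraries, n = 5 per group), with all 5 fKO libraries below all Ctrl libraries. Interferon-gamma genes had a mean of -0.38 ± 0.11, including Cxcl10 (-1.0 ± 0.23), Gbp6 (-0.98 ± 0.16) and Gbp10 (-0.93 ± 0.15). Lists of oxidative phosphorylation and mitochondrially encoded RNA lay higher, and general and lipid-associated macrophage lists lower. As in eWAT, 0 lists passed with an estimated correlation.

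The gene-wise test in iWAT covered 13802 genes, of which 1 rose and 3 fell. Besides Stat1 and Lgals3bp (ENSMUSG00000033880, chromosome 11, 118392751 to 118402092), Gm28177 (ENSMUSG00000101628, chromosome 1, 52077261 to 52156087) fell from 16.6 ± 2.56 to 3.49 ± 0.914 FPKM (SD, n = 5 each), a log2 difference of -1.98 ± 0.14 (adjusted p = 0.000365). This predicted gene overlaps Stat1 on the same strand, and 61.9% of its exonic bases lie in Stat1 exons, so its value is not separate from that of Stat1. Gm11868 (ENSMUSG00000050550, chromosome 4, 18844202 to 18845679), a processed pseudogene 98.0% identical to Cyb5r4, rose from 0.971 ± 0.273 to 3.12 ± 0.524 FPKM (SD, n = 5 each), a log2 difference of 1.07 ± 0.13 (adjusted p = 0.0186). Both predicted genes lie outside the naming rule and were named after their values were seen. At an unadjusted p under 0.05 stood 619 genes, 4.48% of those tested, 222 with higher and 397 with lower values. As in eWAT, that share is below the 0.05 that chance alone would give on average. Predicted genes aside, the next genes by p were Gbp6, Bst2 (-0.62 ± 0.10) and Gbp10, each at an adjusted p of 0.115, then Gbp3 (-0.67 ± 0.11), Cmpk2 (-0.60 ± 0.11), Rfc4 (0.52 ± 0.10), Oasl1 (-0.57 ± 0.11) and Zbp1 (-0.84 ± 0.17), with adjusted p values from 0.166 to 0.360.

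Leaving out 1 library at a time moved the iWAT count between 2 and 14 genes. The 14 came without Ctrl replicate 8 and included Ifit3, Ifit3b, Ifit1, Cmpk2, Gbp3, Gbp6 and Gbp10, and 2 (Stat1 and Gm28177) passed without fKO replicate 1, 2, 5 or 6 or Ctrl replicate 7. Stat1 passed in every such fit (adjusted p from 7.38e-05 to 0.00308), while Lgals3bp (0.00779 to 0.187) did not without Ctrl 4, 7 or 9 or any 1 fKO library, and Gm11868 (0.0101 to 0.0902) did not without fKO 1, 2, 5 or 6 or Ctrl 3, 4 or 7. The log2 difference of Lgals3bp lay between -1.26 and -1.11 in the fits it did not pass, and that of Gm11868 between 1.02 and 1.09. The iWAT libraries fell into a deeper set (over 15 M fragments, 2 Ctrl and 4 fKO) and a shallower set (3 Ctrl and 1 fKO), grouped after seeing the data. The Stat1 difference was -1.69 in the deeper and -1.97 in the shallower set, that of Lgals3bp -1.12 and -1.05, and that of Gm11868 1.04 and 1.25. With this depth class as a term, 2 genes passed, Stat1 and Gm28177.

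Among the fixed lists in iWAT, the type I interferon response was lowest in p (37 of 40 members below 0; camera adjusted p = 1.08e-24 and adjusted p = 0.313 with an estimated correlation; fry adjusted p = 0.0480). Over all genes 1 member fell, Lgals3bp, and 19 fell when adjusted over the list alone, among them Zbp1, Ifit3 (-0.81 ± 0.19) and Ifit1 (-0.76 ± 0.20). The exact permutation p of its mean was 0.00794, the smallest possible. The interferon-gamma response (25 of 26 below 0; camera adjusted p = 1.21e-13 and adjusted p = 0.369 with an estimated correlation) had no member past the threshold over all genes and 9 that fell adjusted over the list alone, among them Cxcl10, Gbp6, Gbp10 and Iigp1 (-0.73 ± 0.26). The exact permutation p of its mean was 0.0238. Within the deeper and shallower sets, the means were -0.51 and -0.26 for type I genes and -0.30 and -0.40 for interferon-gamma genes. The MHC class I pathway was lower (23 of 25 below 0, mean -0.18 ± 0.07, B2m -0.28 ± 0.13, H2-D1 -0.32 ± 0.11; camera adjusted p = 2.04e-06 and adjusted p = 0.369 with an estimated correlation). JAK-STAT components were slightly lower (-0.07 ± 0.07, Ifngr1 0.12 ± 0.13, Ptpn11 -0.10 ± 0.11; camera adjusted p = 0.0312 and adjusted p = 0.464 with an estimated correlation). That call ended without Ctrl replicate 3 (-0.04) or 7 (-0.03), with means of -0.12 without Ctrl 9 and -0.04 without fKO 10. MHC class II was not called (mean -0.12 ± 0.16, camera adjusted p = 0.159).

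Mitochondrial, lipogenic and lipolytic lists lay higher in iWAT. Oxidative phosphorylation and TCA cycle genes had 37 of 38 members above 0 and a mean of 0.15 ± 0.06 (Atp5b 0.19 ± 0.10, Cox8a 0.10 ± 0.11; camera adjusted p = 7.63e-12 and adjusted p = 0.369 with an estimated correlation). RNA encoded in mitochondria had 13 of 15 above 0 and a mean of 0.22 ± 0.11 (mt-Cytb 0.37 ± 0.15, mt-Co1 0.30 ± 0.16; camera adjusted p = 4.41e-07 and adjusted p = 0.464 with an estimated correlation). In the deeper and shallower sets, the former list differed by 0.18 and 0.11 and the latter by 0.27 and 0.08. Lipogenesis (0.17 ± 0.11, Scd1 0.26 ± 0.16, Dgat2 -0.11 ± 0.26) had a camera adjusted p of 0.000422, fatty acid oxidation (0.10 ± 0.08, Acadm 0.14 ± 0.09, Etfb 0.06 ± 0.08) of 0.000991 and thermogenic genes (0.17 ± 0.23, Cox8b 0.67 ± 0.38, Slc36a2 -0.01 ± 0.22) of 0.0316. The adipocyte list (0.08 ± 0.10, Fabp4 -0.68 ± 0.57, Cfd 0.64 ± 0.59) had a camera adjusted p of 0.0318 and lipolysis (0.10 ± 0.08, Plin1 0.23 ± 0.12, G0s2 -0.12 ± 0.15) of 0.0331. Each of these 5 lists had an adjusted p = 0.464 with an estimated correlation. The thermogenic rise was carried by fKO replicate 10 (0.89 from the Ctrl mean). Without it the mean turned to -0.01 (camera adjusted p = 0.548), and the call also ended without Ctrl 7 (0.11). The thermogenic mean was 0.11 without Ctrl 9, 0.26 without fKO 2 and 0.27 without Ctrl 4. In the skeletal muscle list, fKO 10 lay at 3.04 and Ctrl 4, the Ctrl library highest in thermogenic genes (0.41), at 5.05 from the Ctrl mean. With the skeletal muscle list mean as a covariate, added after seeing the data, the thermogenic list in iWAT had a mean of 0.11 (camera adjusted p = 0.0424). Slc36a2 turned above 0 without fKO 1 (0.13), fKO 5 (0.05) or Ctrl 8 (0.14), and Dgat2 without fKO 1 (0.01) or Ctrl 8 (0.07). The fatty acid oxidation call ended without fKO 10 (0.05). The adipocyte call ended without fKO 10, Ctrl 4 or Ctrl 7 (0.06 each), with means of 0.16 without Ctrl 3 and 0.05 without Ctrl 8. Its mean turned to -0.05 with the macrophage list mean as a covariate, added after seeing the data, and to -0.04 without members shared with other lists, and it was not called in either case. The lipolysis call ended without fKO 5 (0.07), fKO 10 (0.09), Ctrl 4 (0.08) or Ctrl 9 (0.08), with a mean of 0.16 without Ctrl 3.

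The immune lists called in iWAT lay lower, while resident macrophage genes (0.10 ± 0.19, 8 of 12 members above 0, camera adjusted p = 0.527) and T and NK cell genes (-0.17 ± 0.19, camera adjusted p = 0.0941) were not called. Macrophage genes had 20 of 21 members below 0 and a mean of -0.26 ± 0.16 (Lyz2 -0.31 ± 0.20, C1qb -0.21 ± 0.15; camera adjusted p = 6.26e-06), and lipid-associated macrophage genes a mean of -0.52 ± 0.33 (Ctsl -0.26 ± 0.14, Fabp5 -0.18 ± 0.32; camera adjusted p = 5.61e-05). Inflammatory mediators had a mean of -0.30 ± 0.21 (Ccl7 -0.82 ± 0.38, Ccl9 -0.28 ± 0.18; camera adjusted p = 0.00578) and ER stress genes one of -0.10 ± 0.04 (Hspa5 -0.21 ± 0.09, Hsp90b1 -0.02 ± 0.09; camera adjusted p = 0.0474). These 4 lists each had an adjusted p = 0.464 with an estimated correlation. Complement (-0.10 ± 0.12, Serping1 -0.17 ± 0.14; camera adjusted p = 0.0159 and adjusted p = 0.571 with an estimated correlation) and granulocyte and mast cell genes (-0.25 ± 0.17, Cma1 -0.39 ± 0.29, Mcpt4 -0.30 ± 0.25; camera adjusted p = 0.0417 and adjusted p = 0.526 with an estimated correlation) were lower, as were proliferation genes (-0.13 ± 0.15, Pcna -0.06 ± 0.06, Ube2c -0.07 ± 0.75; camera adjusted p = 0.04 and adjusted p = 0.649 with an estimated correlation). The inflammatory mediator call ended without fKO 10 (-0.22), with a mean of -0.46 without fKO 2. The ER stress call ended without fKO 5 (-0.10), 6 (-0.11) or 10 (-0.09) or Ctrl 3 (-0.07) or 4 (-0.09), and that of complement without fKO 10 (-0.01), Ctrl 4 (-0.08) or Ctrl 7 (-0.06), with a complement mean of -0.17 without fKO 1. The granulocyte and mast cell call ended without fKO 2 (-0.24), 5 (-0.21) or 10 (-0.19) or Ctrl 3 (-0.30), 7 (-0.13) or 9 (-0.27). The proliferation call ended without fKO 1 (-0.06), 5 (-0.13) or 10 (-0.13) or Ctrl 4 (-0.03), 8 (-0.11) or 9 (-0.14), with a mean of -0.22 without Ctrl 3. Ube2c turned above 0 without fKO 1 (0.22), 2 (0.0021) or 6 (0.17) or Ctrl 4 (0.65), and Hsp90b1 without Ctrl 3 or fKO 10 (0.01 each). In all, camera called 19 of 33 lists, 8 up and 11 down (12 without fKO 10). With an estimated correlation 0 were called, by fry 2 (type I interferon and the neighbourhood of Adipoq) and by the adjusted exact permutation test 0. As in eWAT, group size and the number of tests left the last test little room to call a list. With the macrophage list mean as a covariate, added after seeing the data, 8 lists were called in iWAT and the proliferation mean turned to 0.0085.

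**Figure D2:**
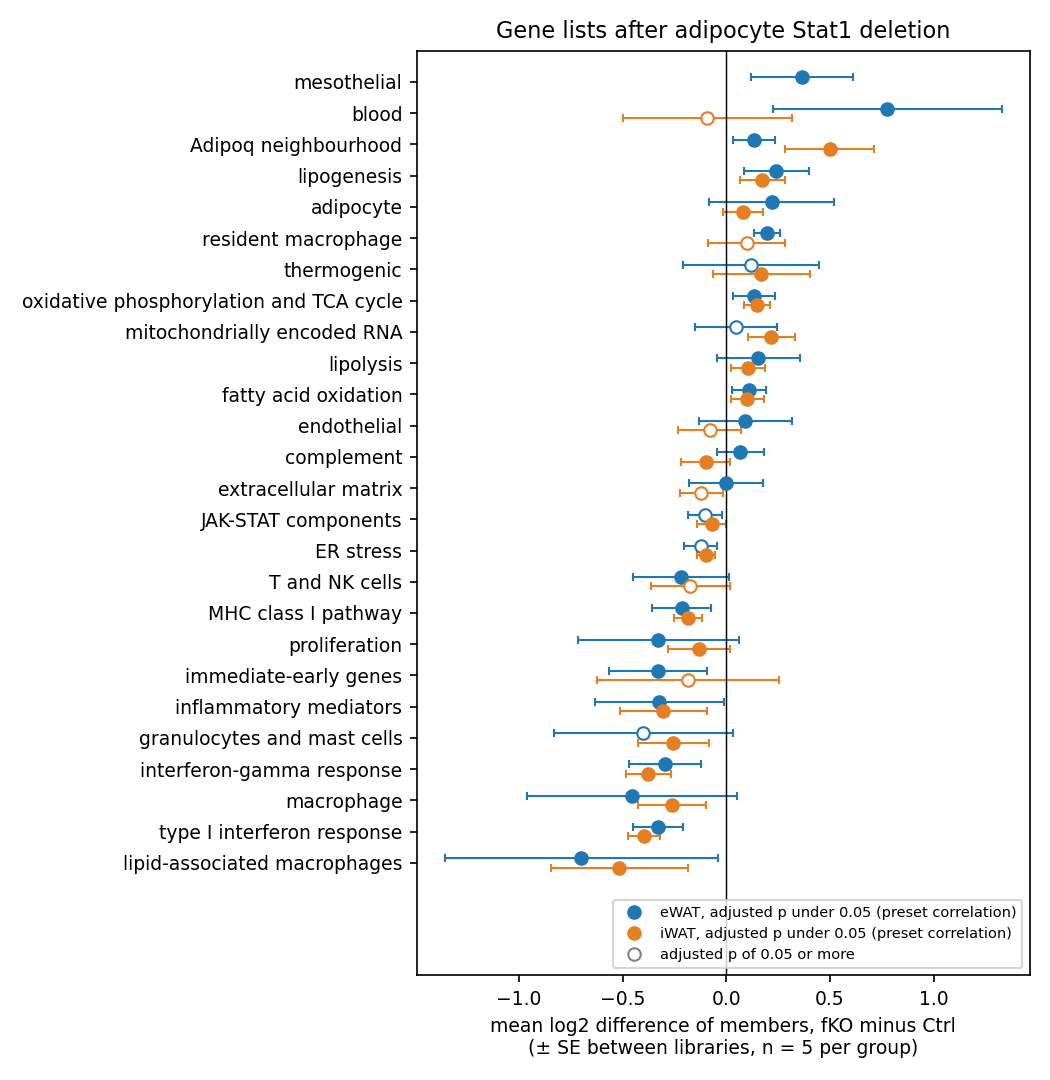
Mean log2 difference (fKO minus Ctrl) of each list called in either depot, with SE between libraries (5 per group). Filled points mark an adjusted p under 0.05 at the preset correlation; the type I interferon list lies at -0.33 in eWAT and -0.40 in iWAT.

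Of the adipokine, insulin and inflammation genes fixed for naming in both depots, none passed the test over all genes. In eWAT the adipokine genes Adipoq and Lep differed by 0.25 ± 0.35 and 0.01 ± 0.11, and in iWAT by -0.07 ± 0.13 and -0.33 ± 0.21. With a library left out, Adipoq ran from 0.06 (without fKO 1) to 0.48 (without Ctrl 3) in eWAT and from -0.12 (without fKO 5) to -0.0031 (without fKO 10) in iWAT. Lep in eWAT turned below 0 without fKO 1 (-0.02), fKO 6 (-0.05) or Ctrl 4 (-0.03), and in iWAT it was -0.15 without Ctrl 8. Slc2a4, the insulin-responsive glucose transporter, differed by 0.09 ± 0.41 in eWAT and 0.26 ± 0.20 in iWAT. Its eWAT value turned to -0.17 without fKO 1 and -0.10 without fKO 5, and was 0.33 without Ctrl 3, which stood apart from the other Ctrl libraries (62.5 against 24.7 to 32.2 FPKM), and 0.36 without fKO 10. Its iWAT value ran from 0.16 (without Ctrl 8) to 0.42 (without Ctrl 3). The insulin signalling list was not called in eWAT (0.06 ± 0.14, camera adjusted p = 0.145) or iWAT (0.06 ± 0.08, camera adjusted p = 0.129). The macrophage genes Adgre1 (-0.58 ± 0.60 in eWAT, -0.39 ± 0.22 in iWAT) and Itgax (-0.83 ± 0.66, -0.81 ± 0.43) had lower values that did not pass. In eWAT, Adgre1 ran from -0.15 (without fKO 1) to -0.91 (without Ctrl 3) and Itgax from -0.27 (without fKO 1) to -1.19 (without fKO 10). The interferon-gamma targets Cxcl9 (-0.45 ± 0.26, -0.41 ± 0.20), Irf1 (-0.26 ± 0.18, -0.33 ± 0.13), Cd274 (-0.10 ± 0.10, -0.16 ± 0.18) and Ciita (-0.10 ± 0.29, -0.14 ± 0.14) also had values below 0. Without fKO 1, Ciita in eWAT turned to 0.16 and Irf1 there was -0.09. With a library left out, Cd274 ran from -0.19 to -0.07 in eWAT and from -0.28 to -0.05 in iWAT. Ciita ran from -0.27 to 0.16 in eWAT and from -0.22 to -0.08 in iWAT. Ucp1, the thermogenic uncoupling protein, differed by 0.51 ± 1.04 and -0.55 ± 0.55. Its eWAT value rested on fKO replicate 2, at 71.3 FPKM against 0.123 to 1.049 in the other fKO libraries, without which the gene was under the filter. In iWAT it was -0.04 without Ctrl 3. Ifng lay under the filter in both depots, at 0.151 ± 0.121 against 0.0949 ± 0.122 FPKM in eWAT and 0.140 ± 0.134 against 0.224 ± 0.230 FPKM in iWAT (Ctrl against fKO, SD, n = 5 each).

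Interferon genes had lower values in both depots, and 1 gene passed the interaction test. Of 66 interferon genes measured in both depots, 58 had values below 0 in both, 35 of the 40 type I genes and 23 of the 26 interferon-gamma genes. Fmo3 (ENSMUSG00000026691, chromosome 1, 162953800 to 162984528) was that gene, with iWAT minus eWAT at -1.39 (interaction adjusted p = 0.0265). In iWAT it lay far under the filter, at 0.00998 FPKM in Ctrl and 0.0237 in fKO (n = 5 each), where a pseudocount of 1 holds any log2 difference near 0. The interaction value of this gene therefore restates its eWAT rise and does not show that its effect differed between depots. The interaction test covered 14195 genes, with 252 (1.78%) at an unadjusted p under 0.05, again below the share that chance alone would give on average. Leaving out any 1 library ended the call (Fmo3 adjusted p from 0.0505 to 0.0806 where it was tested), and 0 genes passed with a pseudocount of 0.1, a filter at 5, array weights or the replicate block.

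No gene passed in both depots, where independent lists would share 7.52e-05 higher and 0.000226 lower genes; in limma at an unadjusted p under 0.05, 12 genes were higher in both (1.56 for independent lists) and 36 lower in both (5.73), of 13290 tested in both, and 1 gene went opposite ways. Among the 36 were Stat1, Lgals3bp, Bst2, Ifit1, Ifit3, Gbp6 and Gbp10. Among the 12 were AC156572.1 and AC156572.2, which overlap each other, Gm11868, Bckdhb, Zfp949, Rfc4 and Eif4a2. For these, explanations tied to the Cre transgene are weighed below, so their number does not show a shared response to Stat1 loss. With all 20 libraries in 1 fit, 3 genes passed in both depots: Stat1, Gm28177, which is not separate from it, and the pseudogene AC156572.1. Across genes, which are not independent replicates, Spearman's rho between the log2 differences of the depots was 0.296, and 0.289 without Stat1 and the interferon lists. Each number has the same genotype in both depots, but the tables do not show whether libraries of the same number came from 1 animal. The values for independent lists hold only if those libraries did not. When libraries were regrouped by number in the same way in both depots, a test added after seeing the data, 19 of 100 splits gave at least the 48 genes of the real one and 11 as large a rho, the real one included. The medians of the other splits were 14 genes and 0.177. The agreement across genes thus lay above that of most splits, but enough others matched it that chance was not excluded. No list's effect passed the test of a difference between depots (smallest exact permutation p = 0.201, adjusted p = 0.966, over 33 lists). This test split the depots separately, as if they shared no animals, and was not run with the same split in both.

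**Figure D3:**
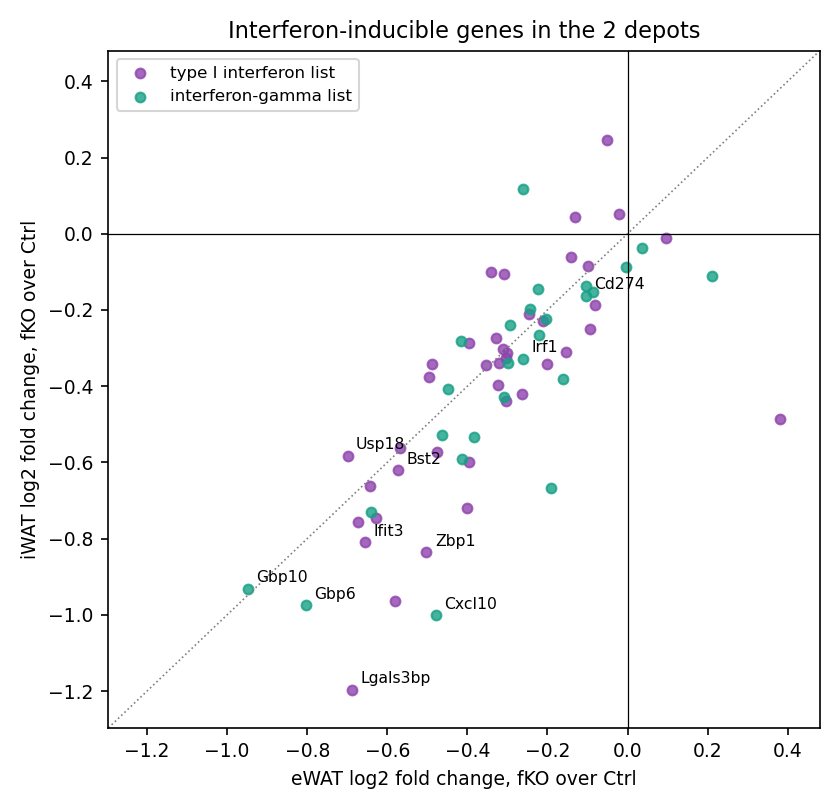
Log2 difference (fKO minus Ctrl) in eWAT against that in iWAT for 40 type I and 26 interferon-gamma response genes; each point is a gene, and the dotted line marks equal values. Of the 66 genes, 58 lie below 0 on both axes.

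Several genes beside Adipoq, the gene whose promoter drives Cre, had higher values in fKO. The fixed Adipoq neighbourhood list rose in iWAT (mean 0.50 ± 0.21 over 8 genes, 5 of them above 0; camera adjusted p = 0.00376 and adjusted p = 0.340 with an estimated correlation; fry adjusted p = 0.0480). Adjusted over the list alone, Rfc4 (0.52 ± 0.10), Eif4a2 (0.62 ± 0.19) and Kng2 (0.83 ± 0.23) rose, and none passed over all genes. The list call ended without fKO replicate 2 (0.36, camera adjusted p = 0.0989). In eWAT the list mean was 0.13 ± 0.10 over 7 genes, 4 of them above 0 (camera adjusted p = 0.0417 and adjusted p = 0.407 with an estimated correlation), with Eif4a2 at 0.57 ± 0.22 and Dnajb11 at -0.15 ± 0.18. That call ended without fKO 2 (0.11), 6 (0.13) or 10 (0.07) or Ctrl 3 (0.10) or 9 (0.12). Rfc4 and Eif4a2 overlap by 194 exonic bases. The neighbourhood of Stat1, without Stat1 itself, was not called in eWAT (-0.10 ± 0.08, camera adjusted p = 0.527) or iWAT (0.06 ± 0.10, camera adjusted p = 0.447).

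**Figure D4:**
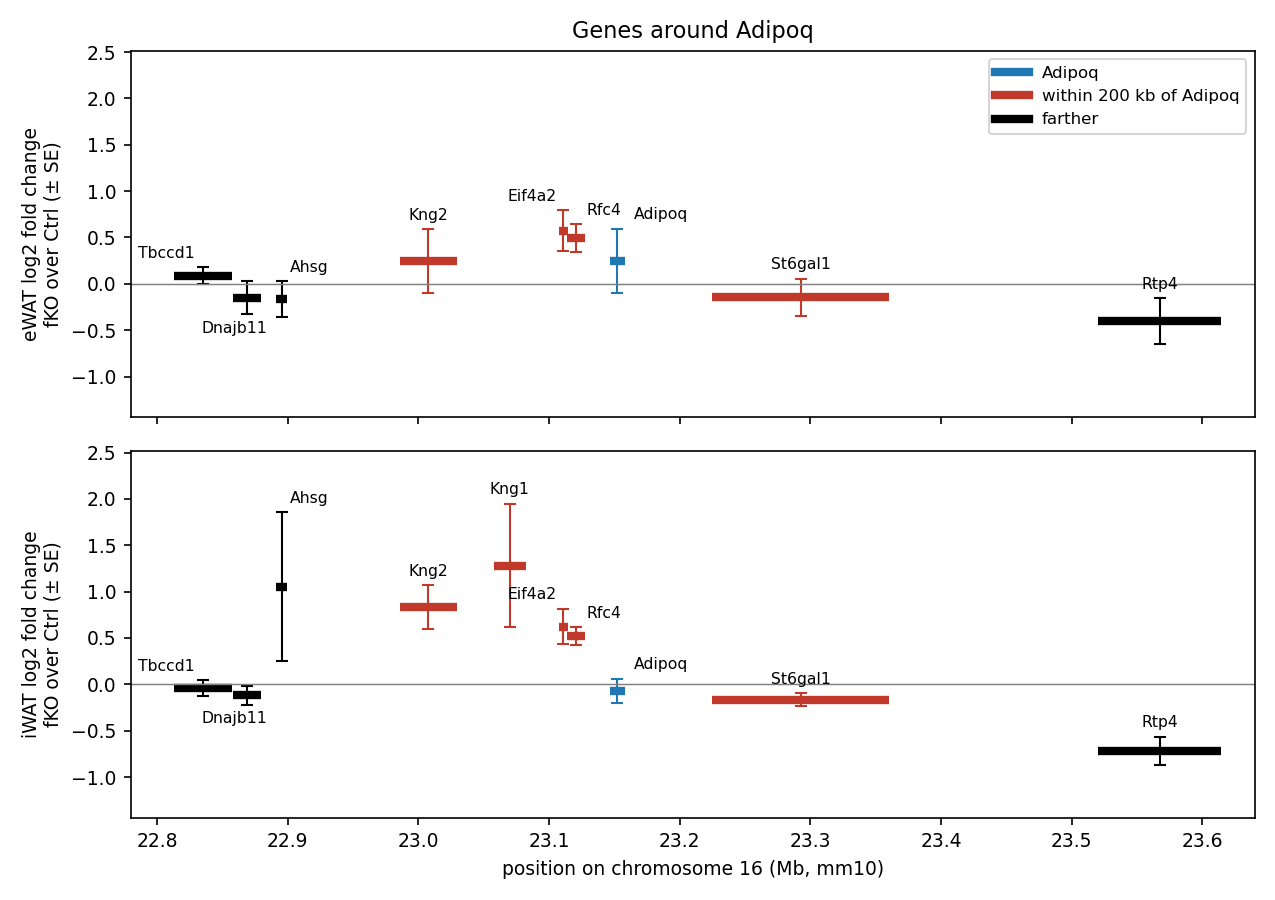
Log2 difference (fKO minus Ctrl, with SE) of genes around Adipoq on chromosome 16 (mm10) in eWAT and iWAT. Blue marks Adipoq, red genes within 200 kb of it and black genes farther away; Rfc4 lies at 0.49 in eWAT and 0.52 in iWAT.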

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

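The checks in this part were set before the data were examined. In each group of 5 libraries, the highest or lowest value was compared with the rest, and 30 of 326 groups examined had a value set far apart by Dixon's criterion, where chance gives about 1 in 20. Values are FPKM for genes and mean log2 values for lists.

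In eWAT, Ctrl replicate 3 stood apart in 10 of these. It was below the other Ctrl libraries in Adgre1 (37.14 against 105 to 135), Itgax (23.1 against 56.3 to 72.7), Lgals3 (481.9 against 1601 to 2529), Atf3 (24.68 against 67.4 to 96.5), Pcna (37.74 against 78.7 to 94.0) and Stmn1 (16.18 against 35.0 to 39.9). It was also below them in the list means for macrophages (5.824), extracellular matrix (5.654) and proliferation (1.937), and above them in Slc2a4 (62.54 against 24.7 to 32.2). Ctrl replicate 9 was high in AC156572.1 (7.15 against 3.81 to 4.48) and low in Fabp4 (2687 against 8292 to 12330). Among fKO libraries of eWAT, replicate 2 was high in Ucp1 (71.34 against 0.123 to 1.049) and Cd274 (7.664 against 5.25 to 5.78). In the same group, replicate 10 was low in Fabp4 (2383 against 10340 to 15980) and replicate 1 low in Saa3 (25.54 against 48.1 to 59.3).

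In iWAT, Ctrl replicate 8 was below the other Ctrl libraries in Ifit1 (2.575 against 5.41 to 6.85), Cmpk2 (3.194 against 4.35 to 4.86), Hsp90b1 (96.18 against 119 to 129) and Serping1 (253 against 346 to 389). Ctrl replicate 3 was low in Itgax (1.412 against 6.42 to 10.1) and in the inflammatory mediator list mean (2.543), and high in the adipocyte list mean (8.855). Ctrl replicate 4 was high in Ube2c (71.13 against 4.50 to 5.54) and Ctrl replicate 7 in Cma1 (49.94 against 21.7 to 27.1). Among fKO libraries of iWAT, replicate 10 was low in Pcna (33.34 against 37.3 to 38.5) and in the list means for the type I interferon response (3.051) and JAK-STAT components (3.424), and high in the thermogenic list mean (3.702). In the same group, replicate 2 was low in Cox8a (728.9 against 960 to 1058).

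Fmo3 passed the interaction test between depots, with iWAT minus eWAT at -1.392 on the log2 scale (limma adjusted p = 0.0265). In iWAT it lay at 0.00998 FPKM in Ctrl and 0.0237 in fKO, where a pseudocount of 1 holds its difference near 0, so the value restates the eWAT rise and shows no differing effect. With a pseudocount of 0.1 it did not pass (adjusted p = 0.9999, over a range of 0.0103 to 0.9999 among its alternatives). Leaving out any 1 library moved this adjusted p to between 0.0505 and 0.0806 where Fmo3 was tested.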

How the results depend on the processing

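The covariate and protein-coding tests in this part were chosen after the results were seen; the others were planned. For the main results, 135 of 162 values under alternatives other than leaving out libraries kept their direction and side of the threshold, or stayed within 1.5 times the main count. With a library left out, it held for 103 of 140 values. For the other named genes and lists it held for 1922 of 2091 and 1459 of 1593 values. Stat1 passed in iWAT under every alternative that was fitted to it, and both interferon lists passed camera in both depots under every alternative fitted to lists but the estimated correlation (the replicate block was not). By fry the type I list passed in iWAT alone (adjusted p = 0.0480, against 0.152 to 0.577 for the others), and by the adjusted exact permutation test neither list did (0.274 to 0.606). The last test had little room to call a list. The type I list in iWAT had the smallest possible exact permutation p (0.00794) and still an adjusted p of 0.274. The lack of calls by that test therefore decides nothing for these lists. The eWAT interferon-gamma mean was -0.1409 with array weights, -0.1913 and -0.1958 with the macrophage and log2 depth covariates and -0.1865 without fKO 1. Rescaling moved the median of all genes by at most 0.0416 (log2).

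Genes passing in eWAT numbered 4 without the filter, 1 at a filter of 5, 4 with all 20 libraries in 1 fit, 0 for protein-coding genes only and 6, 0, 0 and 1 with macrophage, log2 depth, blood and mesothelial covariates. Leaving out a library gave 0 to 4 (0 without Ctrl 3, 4, 7 or 8 or fKO 6 or 10, 4 without fKO 2). In iWAT they numbered 2 without the filter, 1 for protein-coding genes only (Stat1), and 2 with the macrophage covariate or depth class. The 2 were Stat1 and Gm28177 each time, so Lgals3bp passed in none of these fits. Leaving out a library gave 2 to 14 there (14 without Ctrl 8). With protein-coding genes only, the pseudogenes are no longer tested; the cause was not tested for the rest. Stat1 in eWAT passed with all 20 libraries (-1.447, limma adjusted p = 0.00254) and with the macrophage covariate (-1.274, adjusted p = 0.0260), and ranged from -1.606 (without fKO 2, where it passed, adjusted p = 0.0424) to -1.267 with a library left out. Over all its alternatives the adjusted p went up to 0.9999. The overlap of calls was 3 with all 20 libraries (Stat1, Gm28177 and AC156572.1) and 2 with the macrophage covariate (Stat1 and Gm28177). With a library left out it was 0 to 1 (Stat1 without eWAT fKO 2, AC156572.1 without iWAT Ctrl 8). The interaction had 0 genes with a pseudocount of 0.1, a filter of 5, array weights, the replicate block and any library left out (0 to 0).

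With an estimated correlation, 0 lists passed in either depot, and the interferon-gamma and type I means, unchanged by construction at -0.294 and -0.3291 in eWAT and -0.3753 and -0.3956 in iWAT, had adjusted p values of 0.464, 0.369, 0.369 and 0.313. Lists called in iWAT numbered 8 with the macrophage covariate, and 12 (without fKO 10) to 22 with a library left out. Lists that turned direction in eWAT were T and NK cells with array weights (-0.02848), the adipocyte (-0.02354), endothelial (-0.03263) and proliferation (0.01954) lists with the macrophage covariate, and the macrophage (0.033), lipid-associated macrophage (-0.05064), adipocyte (-0.07297), endothelial (-0.03813) and proliferation (0.07164) lists with the blood covariate. For lipid-associated macrophages, and for T and NK cells, camera's direction turned while the mean stayed below 0. The endothelial mean ran from -0.04601 (without Ctrl 8) to 0.2056 with a library left out, and the iWAT thermogenic mean from -0.01245 (without fKO 10, camera direction up) to 0.2712. In iWAT the adipocyte (-0.04678) and proliferation (0.008547) lists turned with the macrophage covariate. The cause was not tested.

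The planned count-based tests were not run, since the tables hold no counts. Depth limits what the tables show for genes near the filter of 1 FPKM, and iWAT libraries differed most in it.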

Other observations

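Of the tests in this part, the depth tests in both depots, the test of extra gene copies beside Adipoq and the splits shared by both depots were chosen after the result was seen. The macrophage covariate was added after seeing the data, and the liver, parent gene and haplotype tests address patterns found in these data.

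Several cell types and pathways fixed beforehand were not called in either depot. Stromal progenitor genes had a mean log2 difference of 0.01 ± 0.13 in eWAT (SE between libraries, n = 5 per group; camera adjusted p = 0.161) and -0.11 ± 0.13 in iWAT (0.0941). Cholesterol synthesis genes lay at -0.10 ± 0.19 (0.515) and -0.15 ± 0.19 (0.0615), hypoxia and angiogenesis genes at 0.03 ± 0.04 (0.152) and 0.01 ± 0.04 (0.717), and B cell genes at -0.06 ± 0.29 (0.493) and 0.05 ± 0.42 (0.463). Dendritic cell genes, measured in eWAT alone, lay at 0.02 ± 0.14 (0.446). Not called in eWAT, though called in iWAT, were JAK-STAT components (-0.10 ± 0.08, 0.0941), granulocyte and mast cell (-0.40 ± 0.43, 0.0660), thermogenic (0.12 ± 0.33, 0.185), ER stress (-0.12 ± 0.08, 0.205) and mitochondrially encoded RNA (0.05 ± 0.20, 0.0941) in eWAT. Not called in iWAT, though called in eWAT, were T and NK cell and resident macrophage genes, extracellular matrix (-0.12 ± 0.10, 0.0556), endothelial (-0.08 ± 0.15, 0.185), immediate-early (-0.19 ± 0.44, 0.356) and blood (-0.09 ± 0.41, 0.767) genes.

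Skeletal muscle genes were spread widely between iWAT libraries without a call (0.63 ± 1.68, camera adjusted p = 0.0805). Myh4, a fast myosin heavy chain, ranged from 0.0420 to 184 FPKM in Ctrl and from 0.0267 to 54.8 in fKO. In eWAT its highest value was 0.104 FPKM. In eWAT, Krt7, an epithelial keratin of the skin and mammary list, was at 3.83 ± 1.21 FPKM in Ctrl and 7.84 ± 3.32 in fKO (SD, n = 5 each; 0.84 ± 0.24). It rose adjusted over the list alone, not over all genes, and its list was not called (0.20 ± 0.27, camera adjusted p = 0.161).

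The lower interferon genes were weighed against macrophage content and depth. With the macrophage list mean as a covariate, the type I list mean stayed below 0 in both depots (-0.25 ± 0.09 in eWAT and -0.39 ± 0.10 in iWAT, the nearer to 0 at -2.79 SE), which argues against fewer macrophages as the whole cause. With log2 depth as a covariate it stayed at -0.41 ± 0.09 in iWAT (-4.67 SE), which argues against depth there. In eWAT it moved from -0.33 ± 0.12 to -0.21 ± 0.11 (-1.95 SE), so depth and genotype cannot be told apart for that depot, since the fKO libraries were shallower and the list rose with depth. Loss of Stat1 in adipocytes, which the design names, stays open as the biological explanation and is a hypothesis.

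The higher genes beside Adipoq may reflect extra gene copies carried by the Cre transgene. Rfc4, Eif4a2 and Kng2 raised this question, so their rise decides nothing, and neither do the small RNAs inside Eif4a2, which went both ways. Of the other measured genes within 200 kb of Adipoq, 1 was left in eWAT (St6gal1, -0.15 ± 0.20) and 2 in iWAT (St6gal1, -0.16 ± 0.07, and Kng1, 1.28 ± 0.67), too few for a test, so the explanation stays open. For Kng1 and Kng2, which are also liver genes, carry-over of liver-type RNA into iWAT cannot be told apart from extra copies there. In iWAT, 12 liver genes differed by 0.95 ± 0.84 and their excess over the genes beside Adipoq was 0.689 SE. Alb was at 51.9 ± 35.7 FPKM in Ctrl and 133 ± 102 in fKO (SD, n = 5 each). Rfc4 and Eif4a2, which overlap, had higher values in eWAT as well, and carry-over into iWAT alone would not account for that. Carry-over into eWAT was not tested. An effect of Stat1 loss on the genes beside Adipoq was not tested.

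The pseudogenes AC156572.1 and Gm11868 were higher in fKO, and their parents Me1 and Cyb5r4 lie near each other on chromosome 9. The parents were not higher (Me1 -0.22 in eWAT and -0.43 in iWAT, Cyb5r4 -0.50 and -0.13), and in both pairs and both depots the pseudogene exceeded the parent by at least 4.62 SE, which argues against parent expression. AC156572.2, which overlaps AC156572.1 on the other strand and was not counted as a pair, exceeded Me1 by at least 2.85 SE. A candidate explanation is a strain haplotype linked to the Cre transgene, whose reads could align to the pseudogenes better than to the reference parents. Among genes within 10 Mb of the parents, 2 of 77 (2.60%, Bckdhb and Zfp949) had an unadjusted p under 0.05 in the same direction in both depots, against 46 of 13193 elsewhere (0.349%; Fisher's exact test, one-sided p = 0.0316). This rests on 2 genes, 1 of them (Zfp949) already among the genes of lowest p named in eWAT. No sequence reads were available to test the haplotype, and an effect of Stat1 loss stays open. The pseudogene Gm1866, which fell in eWAT (-1.19 ± 0.13), has its parent Acp1 on chromosome 12. It was left out of these tests, and a haplotype near Me1 and Cyb5r4 would not account for it.

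Each result across genes was set against 100 splits of the same libraries, the real one included. In eWAT, 2 splits gave as many genes as the real 2 (highest other 2), and in iWAT 2 splits gave as many as the real 4 (highest other 33). Few splits did so, but these shares are not adjusted for the number of results examined and do not exclude chance. The split with 33 genes set Ctrl 4, 7 and 8 with fKO 5 and 6 against the rest. It may reflect a structure of the iWAT samples other than genotype, which was not tested. Those 5 libraries held 3 of the 4 shallower ones, so depth may have a part in it. For the interaction, 8 splits gave as many as the real 1 (highest other 10), so chance was not excluded. For lists called, 3 splits matched the real 21 in eWAT (highest other 21) and 9 matched the real 19 in iWAT (highest other 24). Regroupings other than genotype thus reached the real count in both depots, so chance was excluded in neither. The medians of the other splits were 13 and 11 lists, so a count of lists at the preset correlation is high by itself. For the type I list mean, 2 splits in eWAT moved it as far as the real 0.33 (highest other 0.35). In iWAT 1, the real one, moved it as far as 0.40 (highest other 0.359). Few splits thus moved it as far in either depot, but these shares are not adjusted for the number of lists tested. For interferon-gamma, 16 splits in eWAT moved it as far as 0.29 (highest other 0.461), so chance was not excluded. In iWAT 1 of the 100, the real one, moved it as far as 0.38 (highest other 0.328). The exact permutation p over all splits of iWAT was 0.0238, above the smallest possible, so splits outside these 100 moved it as far. Adjusted over the lists, that exact permutation p was 0.411, so chance was not excluded in iWAT either. With the same split by replicate number in both depots, 19 splits gave as many genes that differed the same way in both depots at an unadjusted p under 0.05 as the real 48 (highest other 577), and 11 gave as large a rho across genes as the real 0.296 (highest other 0.375), so chance was excluded for neither. More than 1 split gave 577 genes, so groupings other than genotype can share many genes between the depots. What those splits have in common was not tested.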
